A study of Mus musculus with 21 samples.

How the data were processed

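The series holds 21 mouse bone marrow samples. Per the labels, DNase-seq was made from ALP, EILP and ILCP in 3 libraries per stage, each from 300 cells digested for 5 minutes with 0.3 units of DNase I. CUT&RUN was made from EILP with 500 cells per library and 3 minutes of nuclease digestion, in 6 libraries titled TCF1 and 4 titled IgG. For 2 more libraries the title names TCF1 and the description names the IgG track, so they were put in no group. Per the file headers, their library number is part of the pooled control of the TCF1 peak calls. If they are TCF1 libraries, as their titles say, that control holds TCF1 signal, which would lower the fold enrichment and raise the background of every TCF1 peak at bound sites. Some libraries are technical repeats of one another. The antibody label reads TCF1 for the IgG libraries too, and their group was taken from the titles.

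The 4 deposited files are peak lists, each called on 1 pooled tag file. Per the file headers, the authors called peaks with MACS version 2.1.1.20160309 at a q cutoff of 0.05, with 50 bp tags, at most 1 tag kept per position and a fragment length of 100 bp. For DNase-seq, per the file headers, tags were shifted by 50 bp so that each extended fragment is centred on the cut, no control was given, and the background came from a 10 kb window. For TCF1 the control was the pooled IgG file, with background windows of 1 and 10 kb. The build is mm9 per the submitters' processing notes, and the last peak lay past the last gene of the GRCm38 gene table on 9 of 21 chromosomes. The aligner settings are not given in the sources used here. Peak height is the deposited pileup signal, the number of extended tags at the summit. Peak strength is the authors' fold enrichment, taken as the ratio of the pileup plus 1 to the local background plus 1. The background of a TCF1 peak was worked out from this relation. Its median was 0.166 tags, so the fold enrichment of most TCF1 peaks follows the tag count closely. The lists also give −log10 of the q-value as deposited. Strength was used only within 1 list, to rank, filter and stratify peaks, to compare medians and as a covariate. The depth after filtering was 12420429 tags for ALP, 11236009 for EILP, 12681410 for ILCP, 2418839 for TCF1 and 2919489 for its control. Pooling removes the spread between libraries, a list with more tags can hold more weak peaks, and presence or absence depends on the cutoff.

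From these lists, the 3 DHS lists were merged into regions wherever peaks shared at least 1 bp, and each region was scored as open in a stage if it held a peak of that list. A region was gained at a step if open at the later stage alone, and lost if open at the earlier stage alone. A region was TCF1-occupied if it overlapped a TCF1 peak by 1 bp. Region strength was the highest fold enrichment among its peaks in the list concerned. Shares were given with 95% Wilson intervals. The share of TCF1 peaks in DHS was set against 1000 circular shifts of the TCF1 list within each chromosome, between the outermost peaks of the 4 lists. Occupancy was compared with Fisher's exact test, two-sided, with sample odds ratios and Woolf intervals, and with Mantel-Haenszel odds ratios over 5 strata of strength, 5 of width or the 25 combinations. TCF1 strength inside and outside DHS was compared by a permutation test of medians with 100000 resamples. Windows of 1 Mb with at least 10 regions were tested with a one-sided binomial test against the genome-wide share, with Benjamini-Hochberg adjustment over the windows of a step. All p-values treat regions of pooled lists as independent and say nothing of the spread between mice or libraries.

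The named items were fixed by rule before the data were examined: the 5 regions or peaks with the highest fold enrichment in each class and the 3 windows of 1 Mb with the most gained or lost regions per step. The windows with the most TCF1 peaks were added. Tests of gene lists, promoter shares and the TCF sequence motif were planned only for an annotation and sequence of the same build and were not run. Alternatives covered the overlap rule, the strength threshold, the number of peaks per list, the distance that counts as absent, the chromosomes used, the way of shifting TCF1 peaks and stratification.

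The functions were tested on simulated lists made from the 70088 EILP peaks. All 13975 removed and 5000 added peaks were recovered as gained and lost. This checks the counting only, because added peaks overlapped no EILP peak and kept peaks were exact copies. The widening of regions by merging unlike peaks was not simulated. With occupancy that depended on strength alone, the unstratified odds ratio had a median of 0.766 over 50 draws and the odds ratio within strength quintiles 0.978. Peaks placed at random gave a fold of 1.16 over circular shifts, and a list with 50% of its peaks placed in DHS gave 50.6% inside. An odds ratio set to 2 was recovered as 1.88 in a single draw, a shortfall that cannot be told from sampling error. The median of 0.978 allows for a small part of a trend with strength left within quintiles of the simulated lists. In the simulation the share gained fell less steeply with strength than in the data. The observed unstratified odds ratio was 0.436, further from 1 than the simulated 0.766. The simulation therefore sets no bound on the trend left within quintiles of the real lists. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.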

Results

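Innate lymphoid cells (ILCs) are lymphocytes without rearranged antigen receptors that arise from lymphoid progenitors in the bone marrow. The series followed open chromatin through 3 successive mouse bone marrow stages: the all-lymphoid progenitor (ALP), the early innate lymphoid progenitor (EILP) and the ILC precursor (ILCP). Open chromatin was measured by DNase-seq, in which DNase I cuts accessible DNA and regions rich in cuts are called DNase I hypersensitive sites (DHS). Each stage had 3 libraries of 300 sorted cells. Binding of TCF1, the HMG-box transcription factor encoded by Tcf7, was measured in EILP by CUT&RUN, in which an antibody directs micrococcal nuclease to the DNA beside the bound protein. There were 6 TCF1 libraries and 4 IgG control libraries of 500 cells each, and both sets include technical repeats. The labels of 2 further CUT&RUN libraries conflicted on the antibody and put them in no group here.

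One peak list per stage and one for TCF1 were analysed, each called on the pooled tags of its libraries, so no value below has a replicate error. Intervals are 95% Wilson intervals for shares and 95% intervals for odds ratios, and they cover the counting of regions only. After filtering, the pooled files held 12420429 tags for ALP, 11236009 for EILP and 12681410 for ILCP, and 2418839 for TCF1 against 2919489 in its control. The TCF1 list therefore rests on shallow data: its median peak height was 5 tags, and 60.7% of its peaks had 5 tags or fewer at the summit. The median height of DHS peaks was 14 tags in ALP and 13 in both EILP and ILCP. Positions are on mouse build mm9, and regions are named by position because no gene annotation of that build was used here. The reporter genotype label of EILP carried a Tcf7 null allele whereas those of ALP and ILCP did not, while the pooled files of all 3 stages were named WT per the file headers. This conflict was not resolved, and if the genotype labels hold, stage and genotype cannot be separated in any comparison with EILP.

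The first question was how the set of open regions differs between successive stages. ALP had 66499 DHS peaks covering 14.9 Mb, EILP had 70088 covering 15.6 Mb and ILCP had 71973 covering 16.3 Mb. Neighbouring stages shared more than distant ones. Of the ALP peaks, 75.9% (75.6 to 76.2) overlapped an EILP peak and 67.5% (67.2 to 67.9) an ILCP peak. Of the ILCP peaks, 69.5% (69.1 to 69.8) overlapped an EILP peak and 62.0% (61.6 to 62.4) an ALP peak. The Jaccard index in base pairs was 0.518 for ALP and EILP, 0.483 for EILP and ILCP, and 0.420 for ALP and ILCP.

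The 3 lists merged into 102384 regions covering 24.8 Mb. Regions open in all 3 stages were the most numerous pattern at 39882, or 39.0% (38.7 to 39.3). A further 9749 regions were open in ALP and EILP and closed in ILCP, and 9487 were closed in ALP and open in both EILP and ILCP. The pattern that closes at EILP and reopens at ILCP was the rarest, at 4190 regions. It was 0.430 (0.415 to 0.446) times as frequent as the ALP and EILP pattern and 0.442 (0.426 to 0.458) times as frequent as the EILP and ILCP pattern. Regions found in a single stage numbered 11608 for ALP, 9878 for EILP and 17590 for ILCP.

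**Figure D1:**
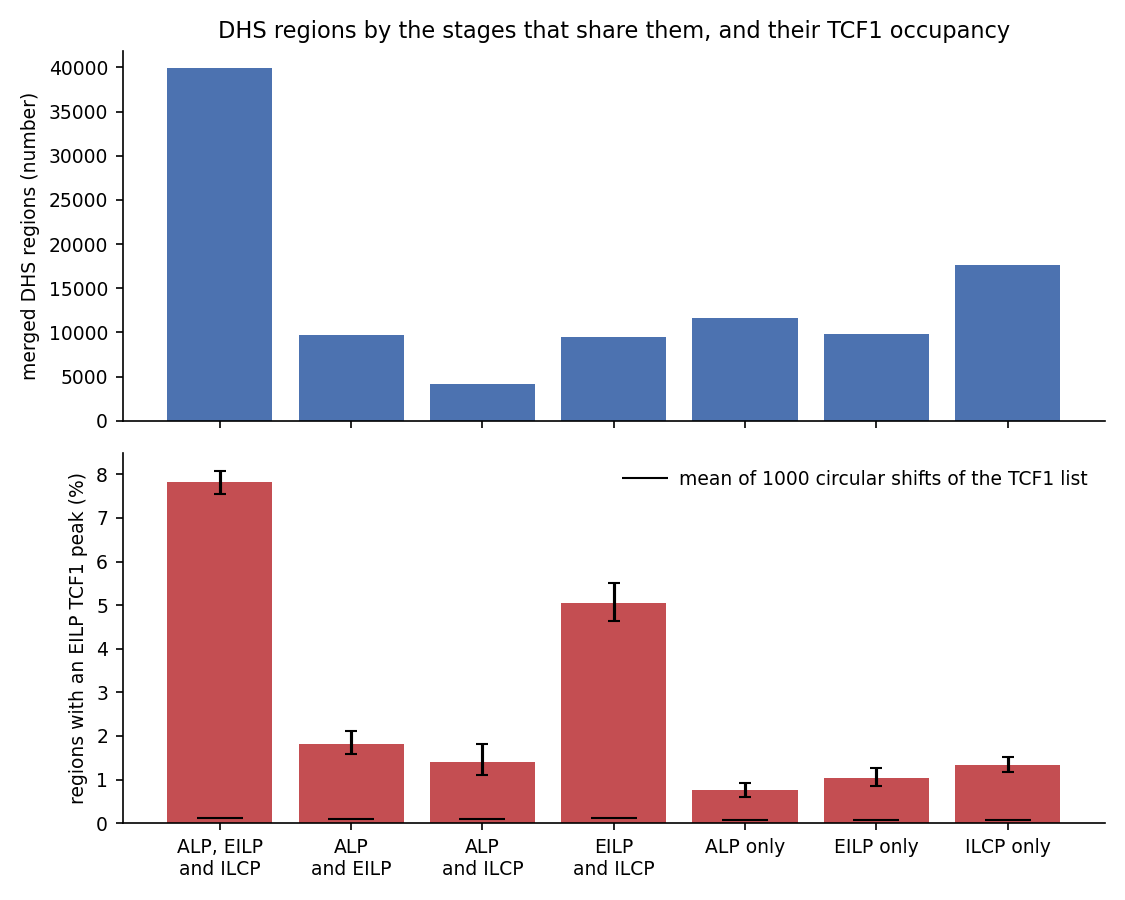
Upper bars give the number of merged DHS regions for each combination of stages, and lower bars the percent of them that overlap an EILP TCF1 peak, with 95% Wilson intervals and the mean of 1000 circular shifts as a black line. Regions open in all 3 stages (39882) and regions shared by EILP and ILCP (9487) had the highest TCF1 occupancy, 7.82% and 5.05%.

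From ALP to EILP, 19365 of the 68996 EILP regions were gained, or 28.1% (27.7 to 28.4), and 15798 of the 65429 ALP regions were lost, or 24.1% (23.8 to 24.5). From EILP to ILCP, 21780 of the 71149 ILCP regions were gained, or 30.6% (30.3 to 31.0), and 19627 of the EILP regions were lost, or 28.4% (28.1 to 28.8). Of the regions gained at EILP, 9487 were still open in ILCP and 9878 were not. The difference between gains and losses at a step equals the difference in the number of regions between the lists. The regions that changed were the weaker ones in the authors' fold enrichment. Median fold enrichment was 5.37 for regions gained at EILP and 8.05 for EILP regions retained from ALP, and median height was 9 against 16 tags. In the weakest quintile of EILP regions 59.0% (58.1 to 59.8) were gained, and in the strongest quintile 1.94% (1.72 to 2.19), which is 268 of 13799 regions. The corresponding shares of ALP regions lost at EILP were 54.7% (53.9 to 55.6) and 1.22% (1.05 to 1.43). Of the stronger-scoring part of the EILP list, split at its median, 3773 peaks (10.5% as peaks, not merged regions) were absent from the whole ALP list.

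**Figure D2:**
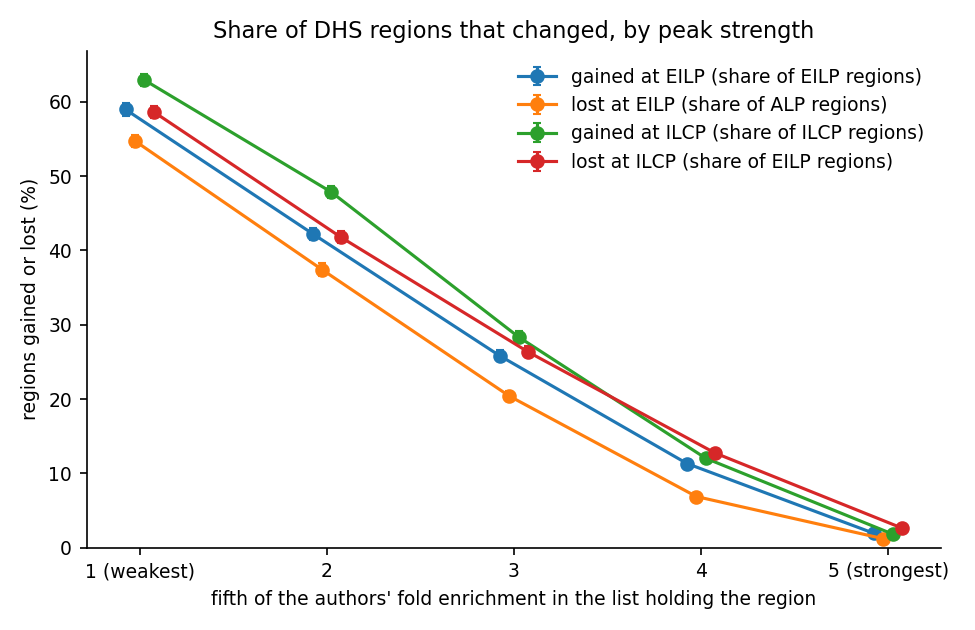
Percent of regions gained or lost at each step (vertical axis) by quintile of the authors' fold enrichment within the list that holds the region (horizontal axis), with 95% Wilson intervals. The share gained at EILP falls from 59.0% in the weakest quintile to 1.94% in the strongest.

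The 5 strongest regions gained at EILP were all still open in ILCP. The region with the highest fold enrichment, 18.2, lay on chromosome 2 at 132029576 to 132029880 and overlapped a TCF1 peak. The next were on chromosome 11 at 58103842 to 58104146 with a fold of 16.4 and on chromosome 6 at 50366787 to 50367255 with a fold of 16.1. The region on chromosome 4 at 135192598 to 135192827 had a fold of 15.4 and overlapped a TCF1 peak, and the region on chromosome 3 at 78832016 to 78832398 had a fold of 15.3. Thus 2 of the 5 overlapped a TCF1 peak. Among all gained regions in the strongest quintile of EILP regions, 25 of 268 (9.33%) did.

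The strongest ALP regions lost at EILP carried no TCF1 peak in any of the 5 cases. They lay on chromosome 7 at 17602416 to 17602690 (fold 16.3), chromosome 12 at 114641047 to 114641400 (fold 15.8), chromosome 19 at 17725292 to 17725638 (fold 15.7), chromosome 16 at 19884264 to 19884599 (fold 15.3) and chromosome 17 at 30661348 to 30661619 (fold 15.0). The chromosome 19 region was open again in ILCP and the other 4 were found in ALP alone. Of all 15798 regions lost at EILP, 11608 were found in ALP alone. In the strongest quintile of ALP regions, 0 of 160 lost regions overlapped a TCF1 peak.

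At the step to ILCP, 17590 of the 21780 gained regions were found in ILCP alone, and 1.34% of those 17590 overlapped a TCF1 peak. The 5 strongest gained regions were all found in ILCP alone and had no TCF1 peak. They lay on chromosome 11 at 57580341 to 57580546 (fold 16.2), chromosome 4 at 9959266 to 9959711 (fold 16.0) and at 44284040 to 44284346 (fold 15.8), chromosome 7 at 28526005 to 28526269 (fold 15.5) and chromosome 15 at 7937430 to 7937648 (fold 15.2). Of the 19627 EILP regions lost at ILCP, 9749 were open in ALP as well, and 1.43% of the 19627 overlapped a TCF1 peak. The 5 strongest EILP regions lost at ILCP were all open in ALP as well and had no TCF1 peak. They lay on chromosome 7 at 3849738 to 3850008 (fold 17.5), chromosome 2 at 49280348 to 49280692 (fold 16.7), chromosome 19 at 9097698 to 9098008 (fold 16.6), chromosome 8 at 67420686 to 67421044 (fold 16.6) and chromosome 13 at 110822119 to 110822522 (fold 15.9).

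Along the chromosomes, an excess of lost regions at EILP passed the test in 2 windows of 1 Mb. On chromosome 12 between 116000001 and 117000000, 27 of 55 ALP regions were lost (49.1%, against 24.1% over the genome). On chromosome 1 between 14000001 and 15000000, 14 of 21 were lost (66.7%). The adjusted p was 0.0433 for both (one-sided exact binomial test, Benjamini-Hochberg over 1652 windows, 90 of which had an unadjusted p under 0.05), and neither window held a region with a TCF1 peak. With 1 Mb windows none passed for gains at EILP (0 of 1668, with 102 at an unadjusted p under 0.05), gains at ILCP (0 of 1722, with 149) or losses at ILCP (0 of 1668, with 123). These counts moved with the settings: with windows of 2 Mb, 0 passed for losses at EILP and 3 for gains at ILCP, and with absence defined as no peak within 500 bp, 2 passed for gains at EILP and 2 for gains at ILCP. The tests set each window against the genome-wide share without holding peak strength fixed. The share lost at EILP was 54.7% in the weakest and 1.22% in the strongest quintile of ALP regions. A window made mostly of weak peaks could therefore pass without a regional effect. The windows with the most changed regions were windows rich in DHS. For gains at EILP they lay on chromosome 4 from 134000001 (38 of 122 regions), from 140000001 (34 of 107) and from 135000001 (33 of 99). For losses at EILP they were on chromosome 11 from 75000001 (29 of 95), chromosome 10 from 67000001 (28 of 68) and the chromosome 12 window already named. For gains at ILCP they were on chromosome 8 from 122000001 (39 of 110), chromosome 17 from 27000001 (38 of 111) and chromosome 5 from 115000001 (35 of 107). For losses at ILCP they were on chromosome 17 from 84000001 (34 of 92), chromosome 2 from 166000001 (34 of 97) and chromosome 11 from 117000001 (34 of 103).

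The next question was where TCF1 binds in EILP relative to the open chromatin of each stage. The TCF1 list held 6679 peaks with a median width of 110 bp. Of these, 57.5% (56.3 to 58.7) lay in EILP DHS, 51.2% (50.0 to 52.4) in ALP DHS and 58.2% (57.0 to 59.4) in ILCP DHS. Circular shifts of the TCF1 list along each chromosome gave 1.06%, 1.01% and 1.1%, so the observed shares were 54.3, 50.9 and 52.9 times chance. The one-sided permutation p was 0.001 for each stage, the smallest that 1000 shifts can give. When each TCF1 peak was instead moved by 20 to 200 kb, which keeps it in the same neighbourhood, the folds were 23.8, 22.4 and 24.0. DHS of all 3 stages held 2983 TCF1 peaks (44.7%, 43.5 to 45.9), and 2298 (34.4%, 33.3 to 35.6) lay in no DHS. Beyond the IgG control of the peak calls, overlap with DHS was not tested against nuclease background in open chromatin.

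TCF1 peaks were more often in EILP DHS but not ALP DHS (652 peaks) than in ALP DHS but not EILP DHS (232 peaks; exact McNemar test, two-sided, p = 7.0e-47). The corresponding numbers for EILP and ILCP were 360 and 409 (same exact test, p = 0.083). These paired tests were added after the data were examined. They take no account of list length, and the EILP list was longer than the ALP list (70088 against 66499 peaks). The folds over circular shifts were close, 54.3 for EILP DHS and 50.9 for ALP DHS. TCF1 was also measured in EILP cells only.

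Stronger TCF1 peaks lay in open chromatin more often. The share inside EILP DHS was 46.2% (43.5 to 48.9) in the weakest quintile of TCF1 fold enrichment and 82.8% (80.7 to 84.8) in the strongest. The median fold enrichment was 5.26 inside EILP DHS and 4.43 outside, a difference of 0.83 (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). In tags the difference was small, with a median height of 6 inside and 5 outside. Where the peaks overlapped, the TCF1 summit lay a median of 55 bp from the DHS summit. The windows of 1 Mb with the most TCF1 peaks were on chromosome 11 from 115000001 with 29 peaks and on chromosome 4 from 134000001 with 27.

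The 5 TCF1 peaks with the highest fold enrichment did not follow this trend. All 5 lay within 25.6 kb of chromosome 11 and none overlapped a DHS of any stage. They were at 52071154 to 52071347 (fold 21.1), 52074972 to 52075162 (fold 20.4), 52070210 to 52070357 (fold 18.2), 52074004 to 52074172 (fold 14.2) and 52095599 to 52095771 (fold 12.6). Their summits lay between 602 and 3606 bp from the nearest EILP DHS summit. With 10 kb added on each side, the same stretch held 10 TCF1 peaks, 1 of which overlapped an EILP DHS. It held 2 DHS in ALP, 8 in EILP and 6 in ILCP. The gene at this stretch was not identified, because no mm9 annotation was used, so whether these peaks lie in Tcf7, of which the genotype labels name reporter alleles, was not checked.

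**Figure D3:**
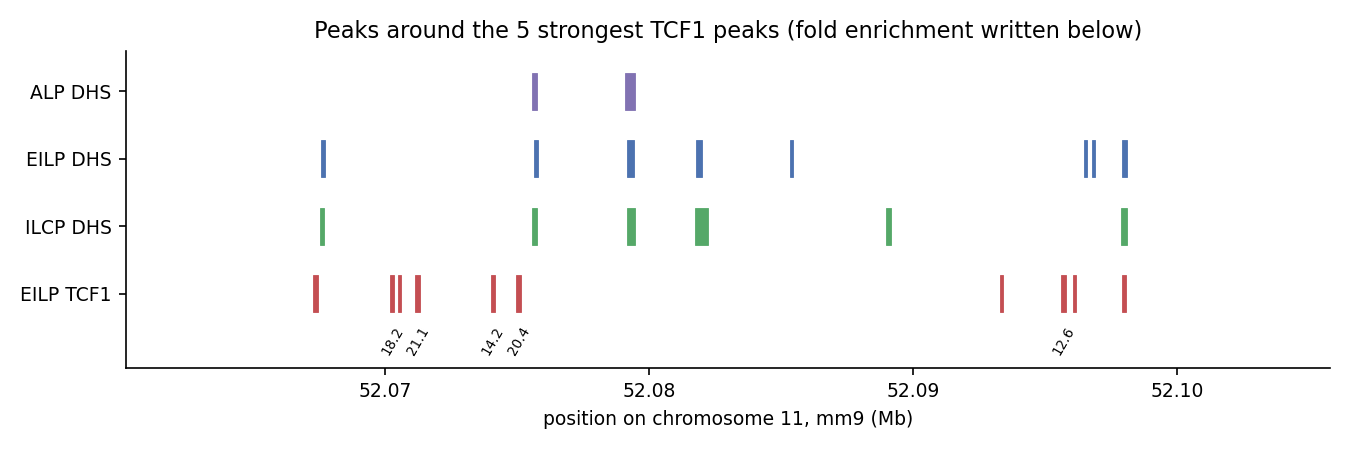
Map of chromosome 11 (mm9, Mb) around the 5 strongest TCF1 peaks, with the peaks of each list drawn to scale in a row of their own and the authors' fold enrichment under those 5 TCF1 peaks. The 5 peaks, with folds of 12.6 to 21.1, fall between the DHS, of which there are 2 in ALP, 8 in EILP and 6 in ILCP.

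TCF1 occupancy was then compared between regions that changed and regions that did not. Among regions gained at EILP, 582 of 19365 (3.01%, 2.77 to 3.26) overlapped a TCF1 peak, against 3295 of 49631 (6.64%, 6.42 to 6.86) of those retained from ALP, an odds ratio of 0.436 (0.398 to 0.477; Fisher's exact test, two-sided, p = 1.1e-86). This difference depended on the size of the regions. Within quintiles of DHS strength the Mantel-Haenszel odds ratio was 0.802 (0.724 to 0.888), within quintiles of region width it was 0.986 (0.894 to 1.09), and within both together it turned to 1.18 (1.06 to 1.30). With EILP peaks in place of merged regions, within quintiles of their own strength and length, it was 1.00 (0.904 to 1.12).

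Regions lost at EILP, which were not DHS at the stage where TCF1 was measured, rarely held a TCF1 peak. Of the ALP regions absent from EILP, 146 of 15798 (0.924%, 0.786 to 1.09) overlapped a TCF1 peak, against 6.64% of those retained, an odds ratio of 0.131 (0.111 to 0.155; Fisher's exact test, p = 6.4e-234). In the next-to-strongest quintile of ALP regions the shares were 0.886% (0.450 to 1.74) of 903 lost regions and 6.49% (6.07 to 6.94) of 12183 retained ones. The odds ratio was 0.395 (0.323 to 0.483) within quintiles of strength and width together.

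EILP regions that stayed open in ILCP held a TCF1 peak more often than those that closed. TCF1 peaks overlapped 3596 of 49369 kept regions (7.28%, 7.06 to 7.52) and 281 of 19627 lost regions (1.43%, 1.27 to 1.61), an odds ratio of 5.41 (4.78 to 6.11; Fisher's exact test, p = 1.9e-251). The difference was present in each quintile of EILP strength, from 4.15% against 1.40% in the weakest to 12.1% against 2.74% in the strongest. Regions gained at EILP showed the same split: 479 of 9487 that were kept at ILCP had a TCF1 peak (5.05%, 4.63 to 5.51), against 103 of 9878 that were lost again (1.04%, 0.861 to 1.26), an odds ratio of 5.05 (4.07 to 6.26; Fisher's exact test, p = 4.8e-64). Within quintiles of strength and width together the odds ratios fell to 2.55 (2.21 to 2.93) for all EILP regions and 2.40 (1.80 to 3.20) for those gained at EILP. Merging with an ILCP peak widens kept regions, and with EILP peaks as units within quintiles of their own strength and length the odds ratios were 3.13 (2.74 to 3.59) and 4.05 (3.21 to 5.10).

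**Figure D4:**
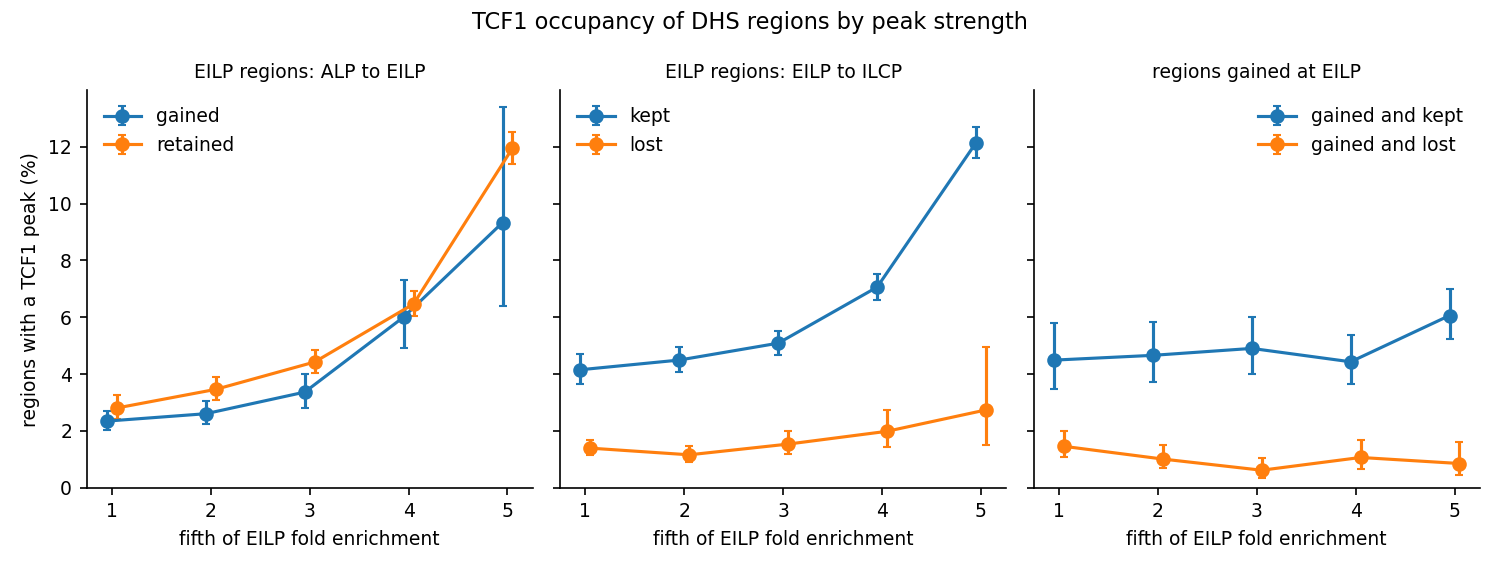
Percent of regions with a TCF1 peak (vertical axes) by quintile of EILP fold enrichment within the set shown (horizontal axes), with 95% Wilson intervals, for EILP regions gained or retained from ALP, EILP regions kept or lost at ILCP, and regions gained at EILP and then kept or lost. Kept regions lie above lost regions in every quintile of the middle and right panels, and gained regions lie below retained regions in every quintile of the left panel, by less (2.35% against 2.81% in the weakest).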

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

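No paired analysis was possible because the 4 peak lists used here each pool their libraries. Signal per library was not analysed here, so no replicate was left out either. The tests of gene lists, promoter share and TCF motif share and their alternatives were not run, since no annotation or sequence of mm9 was used. The following settings were chosen after seeing the data: the stronger peaks of one list against the whole other list, the removal of mitochondrial, Y and wide peaks, a TCF1 q under 0.01, combined strata, own peaks as units, removal of the chromosome 11 cluster, and all settings for windows.

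Of 105 alternative values for the main results, 89 kept their direction, their side of the threshold or, for counts, stayed within 1.5 times. Some settings removed few peaks and could hardly have changed a result. These were autosomes only, the removal of mitochondrial, Y and wide peaks, and the removal of the chromosome 11 cluster. With the stronger-scoring part of each list, split at the median, counts were 10756 gained and 7952 lost at EILP, and 10460 gained and 10471 lost at ILCP. The lists hold fewer peaks by construction, and the shares moved little, to 30.0%, 24.1%, 29.2% and 29.2% from 28.1%, 24.1%, 30.6% and 28.4%. With stronger peaks of one list against the whole other list counts were 3773, 2268, 3830 and 4115 (10.5%, 6.82%, 10.6% and 11.4% of peaks). The TCF1 odds ratio of gained against retained regions was 0.986 (0.894 to 1.09) within width quintiles, 1.18 (1.06 to 1.30) within strength and width quintiles, and 1.00 (0.904 to 1.12) with EILP peaks as units within quintiles of their own strength and length. Windows with excess gain at EILP numbered 2 when absence required no peak within 500 bp, and windows with excess gain at ILCP numbered 2 under that rule and 3 with windows of 2 Mb, against 0 for both. Windows with excess loss at EILP numbered 0 with windows of 2 Mb and 1 with equal list lengths, against 2. The cause was not tested. The other 3 TCF1 odds ratios kept their direction and stayed past the threshold in all 10 alternatives each, and with own peaks as units they were 0.271 for lost, 3.13 for kept and 4.05 for gained and kept regions. The 20 named DHS regions kept their class when absence required no peak within 500 bp. The 2 other rules tried on them, the overlap rule and equal list lengths, could not have changed it. These regions had no overlap with the other list to begin with. The few tags under TCF1 peaks limit which bound regions could be detected, so a region without a peak is not shown to be unbound.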

Other observations

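The tests in this part that were chosen only after the result was seen are those on depth, on regions closed in EILP, on the difference in persistence between gained and retained DHS, on the distance of TCF1 peaks to DHS, and on the chromosome 11 cluster.

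TCF1 in EILP also marked some regions that were not DHS in EILP. Of the regions found in ILCP alone, 235 of 17590 (1.34%, 1.18 to 1.52) overlapped an EILP TCF1 peak, against 87 of 11608 (0.749%, 0.608 to 0.923) found in ALP alone. The odds ratio was 1.79 (1.40 to 2.30; Fisher's exact test, two-sided, p = 1.8e-06), and 1.69 (1.32 to 2.16) within quintiles of region width. These shares were 16.0 and 9.24 times those of circular shifts. Kept DHS held TCF1 more often than lost ones in both older and newer DHS, and whether the strength of this relation differs between them depended on the setting. Among EILP regions retained from ALP the odds ratio was 4.56 (3.91 to 5.31), and 2.42 (2.06 to 2.85) within quintiles of strength and width. For regions gained at EILP these values were 5.05 and 2.40. With EILP peaks as units, within quintiles of their own strength and length, they were 2.76 (2.34 to 3.26) for retained and 4.05 (3.21 to 5.10) for gained peaks, a ratio of 1.46 (1.1 to 1.95). In logistic models the ratio of odds ratios was 1.11 (0.851 to 1.44) for regions, 0.802 (0.614 to 1.05) with log strength and log width as covariates, and 1.19 (0.910 to 1.56) for EILP peaks with their own log strength and log length.

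Stage-specific presence of DHS was concentrated in weak peaks, so chance at the calling cutoff was weighed as its cause. Exchangeable noise predicts that regions open in ALP and ILCP but closed in EILP are about as many as the other patterns of 2 stages. Their ratio to the rarer of those was 0.442 (0.426 to 0.458), which argues against noise as the whole cause. The ratio of gained to lost regions at EILP was 1.23 (1.2 to 1.25), but it only restates that the EILP list is longer, so it decides nothing on depth. A cause particular to EILP, such as its lower depth or its Tcf7 genotype label, predicts that ALP and ILCP are the most alike. Their Jaccard index was instead the lowest, 0.420 against 0.518 for ALP and EILP and 0.483 for EILP and ILCP. This order argues against either as the whole cause. The rarity of regions closed in EILP alone largely fixes the order, so it is not separate evidence. Depth or genotype, if the labels hold, as a part of the cause, noise in part of the weak regions, and stage itself stay open. The pooled lists cannot separate stage from genotype.

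Lower TCF1 occupancy of gained than of retained DHS may reflect the width of the regions rather than when they opened. Strength alone left the odds ratio at 0.802 (0.724 to 0.888), whereas within width quintiles it was 0.986 (0.894 to 1.09), an interval that includes 1. Merging widens regions shared by stages, and with EILP peaks as units within quintiles of their own strength and length it was 1.00. No excess or lack of TCF1 specific to newly opened regions can be claimed from these lists.

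TCF1 peaks outside open chromatin were weighed against the strength of the calls. The odds of lying in EILP DHS were 5.63 (4.71 to 6.73) times higher for the strongest than the weakest quintile, as predicted if many outside peaks are calls that rest on few tags. Stronger TCF1 signal in open chromatin predicts the same rise, so the odds ratio does not decide between them. Even in the weakest quintile 46.2% lay in EILP DHS, against 1.03% for circular shifts. Of the 2298 TCF1 peaks in no DHS, 41.7% lay within 500 bp of one, against 5.33% (SD 0.545) for circular shifts, so calls at random positions do not account for them all. Binding beside DHS and nuclease background beside DHS stay open. The 5 strongest peaks on chromosome 11 were an exception. Of the next 195 peaks by fold enrichment 185 lay in EILP DHS (94.9%, 90.8 to 97.2), so lying outside DHS is not general for strong peaks. Sequence present in extra copies in every library would raise the control as well. The background that the caller set against these 5 peaks was a median of 1.25 times that of all TCF1 peaks (0.781 to 5.00 times). In tags, the median background was 0.207 for the 5 and 0.166 for all TCF1 peaks, against heights of 15 to 25 tags for the 5. The ratio alone left the question undecided, because its range reached 5.00 times. Set against heights of 15 to 25 tags, backgrounds this low argue against extra copies in every library as the source of the 5 peaks. The control may also hold TCF1 signal from the libraries with conflicting labels. The TCF1 peak with the most tags, on chromosome 17 at 39980226 to 39980523, had 43 tags, a fold of 2.5 and a background of 16.6 tags against a median of 0.166. An untested candidate explanation for the chromosome 11 peaks is DNA in the TCF1 libraries alone that does not come from open chromatin, such as a copy of a spliced transcript. The genotype labels name Tcf7 reporter alleles, although the pooled DNase-seq files are named WT, and a copy or construct of Tcf7 would matter most if this stretch is the Tcf7 gene. Neither that nor whether the peaks cover exons was checked, because no mm9 annotation was used. Binding of TCF1 beside its DHS was not tested either.

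A hypothesis written before its test was that regions gained at EILP cluster along the chromosome. Of adjacent EILP regions within 50 kb, 4862 pairs were both gained, against a mean of 4785 (SD 51.2) when labels were permuted 1000 times within chromosome and strength quintile. The ratio was 1.02 (one-sided permutation p = 0.066), so no clustering beyond strength was detected. A companion hypothesis was that TCF1 lies near gained DHS that it does not overlap. A TCF1 peak lay within 10 kb of 13.0% of TCF1-free gained regions and 14.9% of TCF1-free retained regions, and the odds ratio within strength quintiles was 0.713 (0.675 to 0.754), the opposite of what was predicted. Region width and the local density of DHS were not held fixed. The lower share is therefore not shown to relate to when the regions opened.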
